A study of Sus scrofa with 8 samples.

How the data were processed

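Total RNA of pig (Sus scrofa) embryos was amplified, labelled with Cy5 and Cy3 and hybridized to 2-colour Agilent oligonucleotide arrays, with the same sample in both dyes of an array, per the labels. The design has 4 control and 4 experimental arrays, 1 per sample. Groups and replicate numbers were taken from the sample titles. The arrays lay on 2 slides, each scanned once, with control replicates 1 and 2 and experimental replicates 1 and 2 on slide 1 and the others on slide 2. Slide and scan are therefore 1 factor.

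The deposited scanner files hold the spot intensity of each channel (mean signal, median local background and processed signal) and flags, made with Agilent Feature Extraction 9.5.3.1, per the file headers. Other columns used from the deposited files, of the unit other, are the flags for spots well above background, saturated spots and outlier spots. Per the file headers, spatial detrending was on for the processed signal. The deposited series table holds log10 ratios of red over green. Each of its 8 columns equals the log ratio of its array within 0.00494, with a median of 0 in every column, so scale and direction are known and it holds no level. It was not used for a comparison. Other steps are not given in the sources used here.

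Intensities were background corrected with normexp (offset 50) on the mean signal and median local background. They were then normalized by loess within arrays with control spots at weight 0, and by Aquantile between arrays, in limma 3.58.1 under R 4.3.3. The A value, the mean of the log2 red and log2 green signal, is the level of a probe. The log ratio holds no comparison between samples, since both channels carry 1 sample. Each of the 39513 probes has 1 spot, and 1417 control spots were left out. Values of outlier spots were left out, 17 in number among the probes kept. Saturated spots were kept and were at most 1 per array. A probe was kept if it was well above background in both channels on at least 4 of the 8 arrays, which left 19696 probes. Of these, 16246 were above background on all 8 arrays.

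Groups were compared with lmFit and eBayes (limma), experimental minus control, with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05, and no covariate. Gene lists were tested with camera (two-sided, preset correlation 0.01, adjusted over lists with at least 5 measured genes), again with an estimated correlation, and with fry. Counts of members past 0.05 are given over all probes and adjusted over the list alone. The brightest kept probe stood for a gene. Distances between arrays were compared by exact permutation tests over 35 splits or 70 assignments. Genes were named by a rule fixed before the data were examined: up to 15 with the largest increase and 15 with the largest decrease among probes past the threshold with groups that do not overlap and 1 gene symbol, up to 4 members with the smallest p in each list, and the measured genes of 34 fixed genes. The first part gave 20 genes, the second 47 and the third 8, and 69 in all. The 23 lists, the cell type markers and the alternatives were also fixed before the data were examined, apart from those named as later choices.

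Gene symbols came from matching the accession of a probe, without version, to a reference table of the assembly Sscrofa11.1, used for names only. Of the 39513 probes, 1506 matched 1 symbol, 0 matched several and 38007 matched none, giving 432 symbols. Of these, 327 were measured on 697 kept probes. The 39513 probes carry 22824 accessions, and 10113 accessions stand on more than 1 probe, up to 24. Of 175 pairs of probes that share at least 30 bases, 39 (22.3%) carry the same accession. The files name no gene, and no genome was used, so no coordinates are given.

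The fits were tested on simulated data for the comparison of experimental and control embryos. Values for 19696 probes were drawn from the real means and spreads, with 200 probes changed per run in 5 runs. Of probes changed by 0.5 log2, 24.4% were recovered, of those changed by 1, 72.8%, by 2, 96.0%, and by 3, 98.0%. Unchanged probes made up 5.08% of calls, and at most 0 probes were called in runs with no change. The list with the most measured genes (16) was called in 20 of 20 runs with its members shifted by 1 log2. Other lists were not tested in this way. Without a shift, 0 of 20 runs called any list. The exact test of distances gave p under 0.05 in 2 of 20 runs without a shift. The draws gave a probe the same spread on every array and let probes vary independently. In the real data the SD over probes of the difference to the mean of the other arrays of the group was 0.53 log2 for experimental replicate 3. It was 0.24 to 0.34 for the other arrays. The rates therefore hold for the simulated setting.

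Alternatives covered background correction, offset, normalization between arrays, single dyes, the filter on dim probes, the variance model, array weights, the replicate number and the slide as blocks, a plain test per probe, and leaving out each array. Those chosen after the data were seen were each slide alone, slide means removed from the distances, removal of each array's trend on probe GC content, centring on the median of the probes kept, and a limit to genes with several probes in 1 direction. Tables were handled with pandas 2.3.3 under Python 3.11.15 and drawn with matplotlib 3.10.9.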

Results

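Expression was measured in pig embryos at the ovoid stage, when the conceptus before attachment to the uterus begins to elongate. The 8 samples formed 2 groups of 4 embryo RNAs. The control group held day 11 ovoid embryos from a homogeneous population. The experimental group held delayed ovoid embryos from a heterogeneous population, of about day 11.5 according to the series description. The sample labels give day 11 and a length of 7 to 8 mm for both groups, so the age of the experimental embryos differs between the labels and the description. The comparison asks whether the shape of an embryo or the uterine environment it came from better predicts its transcriptome. Each array carried 1 sample in both dyes, a self-self hybridization, and the level of a probe is the mean log2 signal of the red and green channels. Between 18465 and 20568 of 39513 probes were well above background in both dyes on an array, and 19696 probes entered the tests. The labels do not say that the 4 samples of a group came from separate pregnancies, so p-values measure the spread between these samples. The number of arrays limits the precision.

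Probes labelled with a steroid enzyme, a thromboxane enzyme and transcription factors were brighter in the experimental embryos, and probes labelled with a surface sialomucin, a lipoxygenase and a cholesterol transporter were dimmer. Of the 19696 probes, 999 differed between the groups at a Benjamini-Hochberg adjusted p under 0.05, 477 higher and 522 lower in experimental embryos. A change of at least 2-fold was found for 336 of them, 197 higher and 139 lower. The median size of a called change was 0.82 log2. In 997 of the 999, all 4 arrays of one group lay beyond all 4 of the other, as did 3100 (15.7%) of the probes kept, where chance gives 2.86%. The slides were balanced, with 2 arrays of each group on each of 2 slides, and the slide as a block called 970 probes, 833 of them shared. With 2 arrays against 2 the test called 4 probes on slide 1 and 0 on slide 2, where limma gave 3708 and 2839 probes at an unadjusted p under 0.05. Over all probes kept, the changes on the slides had a Pearson's r of 0.527 and 62.9% of probes the same direction on both. Of the 500 probes with the largest change on slide 1, 88.0% changed in the same direction on slide 2, and 91.2% of the 500 with the largest change on slide 2 did so on slide 1. Leaving out 1 array moved the count by over 1.5 times for control replicates 1, 2, 3 and 4 (533, 460, 307 and 553 calls) and experimental replicates 1 and 4 (606 and 647), and the 2-fold count for control replicate 3 (158). Control samples lay on positions 1 and 2 of each slide and experimental samples on positions 3 and 4, so a difference between these positions and the group cannot be told apart. The split of calls depended on the scaling: 477 (47.7%) of 999 calls were increases with between-array quantile normalization, 141 (6.71%) of 2101 with each array centred on the median of all probes, and 641 (36.2%) of 1771 with each array centred on the median of the probes kept. Centring on the median of all probes shifted the median log2 change of the probes kept to -0.27, from 0.002, and 132 of the 477 increases and 520 of the 522 decreases were still called in the same direction.

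The probe labelled POU2F2, an octamer-binding transcription factor known from B cells, had the largest increase among probes with a gene name. Its log2 level was 8.85 ± 0.34 (SD, n = 4) in control and 12.26 ± 0.34 in experimental embryos, a 10.6-fold difference (log2 change 3.41, SE 0.21, adjusted p = 0.000325). The 60-base probe reads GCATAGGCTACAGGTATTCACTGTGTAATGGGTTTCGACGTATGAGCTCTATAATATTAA. The probe labelled CYP19A1, aromatase, which converts androgens to estrogens, rose from 11.69 ± 0.64 to 13.82 ± 0.27, a 4.39-fold difference (log2 change 2.14, SE 0.30, adjusted p = 0.00954). Its change was 2.05 on slide 1 and 2.22 on slide 2, and its sequence is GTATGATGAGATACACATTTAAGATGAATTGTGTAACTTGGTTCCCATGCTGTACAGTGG. TBXAS1, thromboxane synthase, rose 2.86-fold (log2 change 1.52, SE 0.29, adjusted p = 0.024), with the probe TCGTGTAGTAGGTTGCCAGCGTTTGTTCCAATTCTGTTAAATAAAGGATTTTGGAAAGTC. All 4 kept probes of TBXAS1 were higher in experimental embryos, and 1 of the 3 others passed the test.

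Other increases were smaller. DHDH, a dihydrodiol dehydrogenase, rose by 1.24 on the log2 scale, AR, the androgen receptor, by 1.15, and JUN, a subunit of the AP-1 transcription factor, by 1.08. PLIN2, a coat protein of lipid droplets, rose by 0.82, CD247, a chain of the T cell receptor complex, by 0.78, PRKAR1A, a regulatory subunit of protein kinase A, by 0.78, and OBP2B, an odorant-binding protein, by 0.61. The adjusted p of these 7 genes lay between 0.0184 (PLIN2) and 0.0379 (JUN).

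CD34, a sialomucin of blood-forming and endothelial cells, had the largest decrease among named probes. It was well above background on all 4 control arrays (7.80 ± 0.39) and on 0 of 4 experimental arrays, so the difference is a bound: at least 2.55-fold higher in control embryos (adjusted p = 0.00775). The bound sets the mean of the control arrays against the lowest signal among probes well above background on each experimental array, or the probe's own signal where that was higher. CD47, an integrin-associated membrane protein, fell by 0.80 on the log2 scale, CRYL1 fell by 0.71, and NPC1, which moves cholesterol out of late endosomes, fell by 0.69, from 16.07 ± 0.11 to 15.38 ± 0.23. DPEP1, a dipeptidase, fell by 0.68. COASY, the enzyme of the last steps of coenzyme A synthesis, fell by 0.67, from 13.58 ± 0.04 to 12.91 ± 0.11. The neurotrophin BDNF fell by 0.62, DUOX1, an oxidase that makes hydrogen peroxide, fell by 0.61, the glutamate decarboxylase GAD2 fell by 0.58, and the lipoxygenase ALOX15 fell by 0.57. The adjusted p of these 10 genes lay between 0.00708 (COASY) and 0.0458 (GAD2).

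**Figure D1:**
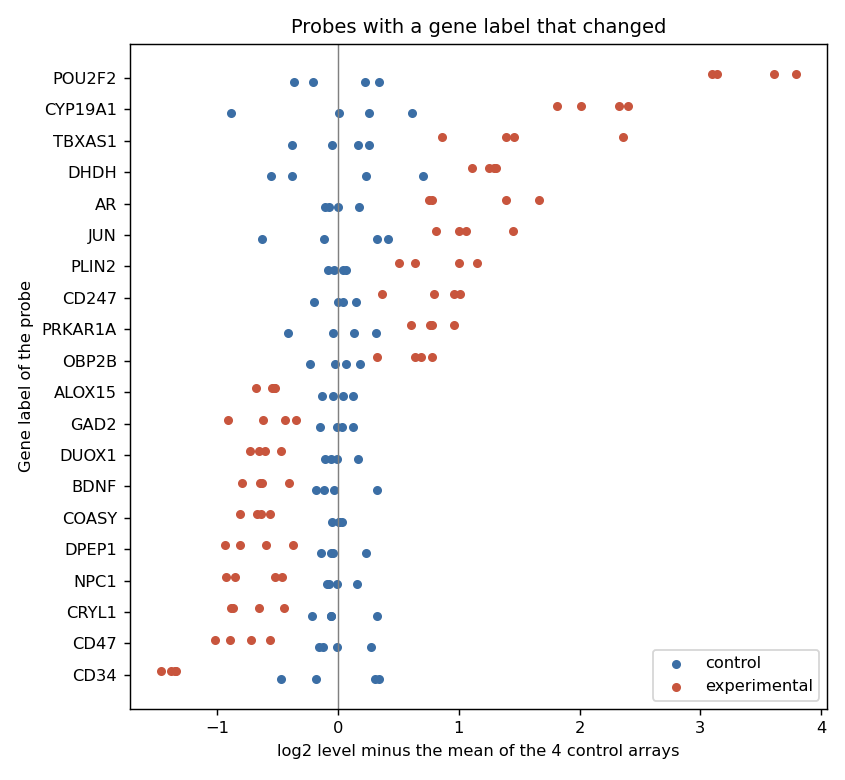
Log2 level of each array minus the mean of the 4 control arrays (horizontal) for the 20 genes named by change (vertical, with the gene label of the probe); each point is 1 array, blue control and red experimental. The points of the groups do not overlap for any of the 20 genes, which was a condition of their selection. The largest increase was that of POU2F2 (3.41) and the largest decrease that of CD34. CD34 was not well above background on any experimental array, so that the difference is a bound (at least 2.55-fold).

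With the slide as a block 19 of the 20 genes passed the test, GAD2 being the exception (adjusted p = 0.0615). With the replicate number as a block 17 of the 20 lost the call, and with a plain test without variance sharing 19 did. Without the filter on dim probes 9 lost it with the same log2 changes: JUN, DPEP1, GAD2, TBXAS1, PRKAR1A, OBP2B, DHDH, CRYL1 and BDNF. With each array centred on the median of all probes, 7 of the 10 increases lost the call and 0 of the 10 decreases: the log2 change was 0.14 for CD247, 0.16 for PRKAR1A, 0.13 for OBP2B, 0.42 for JUN, 0.55 for AR, 0.88 for TBXAS1 and 0.93 for DHDH. POU2F2 (2.86), CYP19A1 (1.48) and PLIN2 (0.48) passed there. With each array centred on the median of the probes kept, JUN, CD247, PRKAR1A, OBP2B, BDNF and ALOX15 lost the call. From processed signals 7 genes did, with log2 changes of 0.93 for JUN, 0.60 for CD247, 0.68 for PRKAR1A, 0.57 for OBP2B, -0.55 for NPC1, -0.75 for GAD2 and -0.23 for DUOX1. Of list genes that did not pass, CYP11A1, HMOX1, ITGB1 and MSN, each with a negative change, passed under both kinds of centring, and PTGS2 passed centred on the median of all probes. POU2F2, CYP19A1, CD34, CD47, COASY, DUOX1 and ALOX15 passed in each of the 8 fits that left out 1 array. The other 13 genes lost the call in at least 1 of those fits, TBXAS1 and PLIN2 in the 4 fits that left out a control array. Counted over all measured genes with a symbol, those past the test with groups that do not overlap numbered 8, 11, 7 and 10 without control replicates 1, 2, 3 and 4. There were 12 without experimental replicate 1 and 33 without experimental replicate 3.

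The gene names have a measured limit. They come from the accession that the array files give for a probe, and probes with the same name did not follow each other across the 8 arrays. The median correlation over arrays was 0.063 for 714 pairs of kept probes with 1 gene name, against 0.003 for random pairs. Of these pairs, 48.9% changed in the same direction, against 49.6% of random pairs. The median correlation was 0.914 for 136 pairs of probes that share 30 bases, whatever their accession. For the 20 named genes, 15 of 22 other kept probes changed in the same direction, and 1 of them passed the test. The other kept probe of CRYL1 changed in the opposite direction, as did 2 of GAD2, where 1 changed in the same direction. The second kept probe of POU2F2 had a log2 change of -0.22 (adjusted p = 0.316), and that of CYP19A1 0.08 (adjusted p = 0.685). Each value given for a gene is the value of the probe so labelled.

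**Figure D2:**
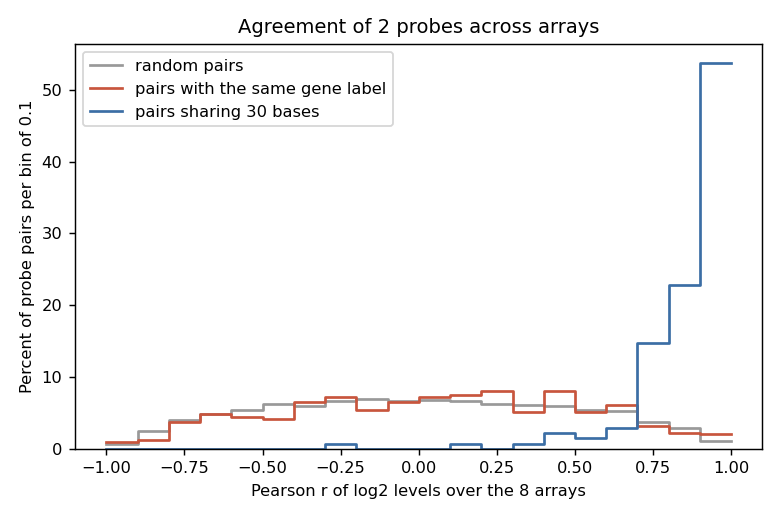
Pearson correlation of the log2 levels of 2 probes over the 8 arrays (horizontal) against the percent of probe pairs in each bin of 0.1 (vertical), for random pairs, pairs with the same gene label and pairs that share 30 bases. A correlation over 0.7 was found for 7.56% of pairs with the same label, 7.61% of random pairs and 91.2% of pairs that share 30 bases.

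The largest changes of all were in probes without a gene name. The probe with the sequence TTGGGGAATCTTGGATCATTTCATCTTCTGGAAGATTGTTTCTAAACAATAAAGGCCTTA, rose 35.5-fold, from 10.04 ± 1.19 to 15.19 ± 0.29 (log2 change 5.15, SE 0.51, adjusted p = 0.00377). The probe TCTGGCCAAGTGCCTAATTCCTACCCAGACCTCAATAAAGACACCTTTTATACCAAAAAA, rose 14.4-fold (log2 change 3.85, SE 0.41). The largest decrease was 8.61-fold in the probe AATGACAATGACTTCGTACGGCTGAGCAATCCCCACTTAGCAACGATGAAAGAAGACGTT (log2 change -3.11, SE 0.25, adjusted p = 0.0012). The probe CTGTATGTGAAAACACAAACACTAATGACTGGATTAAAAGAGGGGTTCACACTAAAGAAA, was 8.22-fold lower (log2 change -3.04, SE 0.43).

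The groups of genes written down beforehand were covered thinly, and 0 of the 7 lists with at least 5 measured genes passed camera. The limit of the gene names given above holds here too. Results of lists, lineages and markers are those of probes so labelled, and missing calls cannot speak for pathways or cell types. Of 23 lists, 7 had no measured gene, which were the epiblast, gastrulation, cholesterol synthesis, glycolysis and hypoxia, ribosome, retinoid and erythroid lists, and 9 had 1 to 4. In the steroid list 9 genes were measured, with a median log2 change of -0.11, a mean of 0.12 and an upward direction in camera. CYP19A1 was the 1 member past the test, over all probes and adjusted over the list alone. CYP17A1, which makes androgens, had a change of -0.68 (adjusted p = 0.121), and without experimental replicate 2 it passed at -0.90 (adjusted p = 0.0241, the lowest of its alternatives, which reached 0.629). STAR, which brings cholesterol to mitochondria, had -0.31 (adjusted p = 0.559), and CYP11A1, the side chain cleavage enzyme, -0.21 (adjusted p = 0.451). The change of HSD3B1 was -0.18 (adjusted p = 0.448), and 1 of its 2 other kept probes passed the test in the same direction (-0.56, adjusted p = 0.0423). CYP19A3, another porcine aromatase gene, had 0.25 (adjusted p = 0.295). The list as a whole had a camera adjusted p of 0.851 and 0.884 with an estimated correlation.

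Among secreted signals and implantation factors of the conceptus, 16 genes were measured, 10 with a positive and 6 with a negative change, and 0 passed over all probes (limma), where 5 passed adjusted over the list alone. These were SERPINE1, an inhibitor of plasminogen activators (0.37, adjusted p over all probes 0.0608), its target PLAU (0.48, 0.105), IL1B2, the conceptus form of interleukin 1 beta (0.51, 0.105), LIF (-0.60, 0.11) and IGF1R (-0.29, 0.117), the last named after its value was seen. The other kept probe of IGF1R passed over all probes in the same direction (adjusted p = 0.0209), and it was not well above background on any experimental array. IL1B2 passed over all probes without experimental replicate 3 (0.66, adjusted p = 0.0143, with 0.01 to 0.708 over its alternatives). With the slide as a block LIF passed over all probes (adjusted p = 0.0188), the lowest of its alternatives, which reached 0.266. IGF2 had a change of 0.85 (SE 0.73, adjusted p = 0.566), which was 1.81 on slide 1 and -0.10 on slide 2. Its level was 11.00 in control replicate 4 and 7.24 to 8.31 in the other control replicates. Without control replicate 4 it passed with 1.68 (adjusted p = 0.0334, the lowest of its alternatives, which reached 0.977). IL1B had a change of 0.15 (adjusted p = 0.696), and PTGS2, a prostaglandin synthase, -0.35 (adjusted p = 0.168). The list had a camera adjusted p of 0.685 and 0.846 with an estimated correlation.

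Of 6 measured genes of fatty acid uptake, storage and use, PLIN2 rose and 5 did not pass. The list's median change was 0.20, and its camera adjusted p was 0.657, with 0.816 with an estimated correlation. HMGCS2 had a change of 0.29 (adjusted p = 0.168), HADHA 0.27 (adjusted p = 0.432) and DGAT1 -0.28 (adjusted p = 0.333). HADHA passed without experimental replicate 3 (0.46, adjusted p = 0.034, the lowest of its alternatives, which reached 0.852). The 4 other kept probes of HADHA changed in the opposite direction. In the list of cytoskeleton, adhesion and matrix genes, 0 of 8 measured genes passed by limma, over all probes or adjusted over the list alone. Their median change was -0.29, with MSN at -1.13 (adjusted p = 0.116), ITGB1 at -0.30 (adjusted p = 0.0929), MMP14 at -0.30 and CFL1 at -0.29. The 2 other kept probes of CFL1 changed in the opposite direction. ITGB3 had 0.00 (adjusted p = 0.994), while 1 of its 5 other kept probes passed with -0.91 (adjusted p = 0.0411). The probe that stands for ITGB3 holds a 16-base word found in 27 probes, and without it the list's median change was -0.30. Camera gave an adjusted p of 0.657 for this list and 0.816 with an estimated correlation. Fry, which asks only whether the members move one way on balance, gave 0.0347. The interferon response list had 0 of 6 measured genes past the test, with IRF6 at -0.49, DDX58 at -0.38, MX1 at 0.41 and USP18 at 0.17 (camera adjusted p = 0.851, and 0.884 with an estimated correlation).

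For the cell lineages of the embryo, 5 hypoblast genes and 1 trophoblast gene were measured, and 0 passed by limma. AFP had a change of 0.15, ALB, above background on 1 control and 3 experimental arrays, 0.18, HNF1B 0.24 and GATA6 -0.18 (camera adjusted p = 0.848 for the list, and 0.884 with an estimated correlation). PAG6, a pregnancy-associated glycoprotein of the trophoblast, had a change of -1.01 (SE 0.45, adjusted p = 0.245). All 4 of its kept probes had negative changes, and a dimmer one of them passed the test (adjusted p = 0.0231), which was not well above background on any experimental array. In the lists with 1 to 4 measured genes, CCND2, a cyclin of the G1 phase, had a change of 1.21 (adjusted p = 0.0959), while its other probe passed in the opposite direction (-0.45, adjusted p = 0.0346). TOP2A, a topoisomerase, had -0.26. HMOX1, haem oxygenase, had -0.47 (adjusted p = 0.0747), with the chaperone HSP90B1 at -0.32 and the peroxiredoxin PRDX6 at 0.10 in the same stress list. ACO2, mitochondrial aconitase, had 0.42 (adjusted p = 0.0857), the death receptor FAS 0.32 and the imprinted GNAS -0.12. Leaving out 1 array brought some genes of these lists past the test. They were CCND2 without experimental replicate 4 (0.80, adjusted p = 0.0419, with 0.0419 to 0.337 over its alternatives), HMOX1 without experimental replicate 1 (-0.58, 0.0368, with 0.0368 to 0.489) and ACO2 without experimental replicate 3 (0.49, 0.0494, with 0.0207 to 0.823). IGF2, which is also in the imprinted list, passed without control replicate 4, as given above. Of 3 transport genes, ATP1A1 had -0.30, SLC9A1 -0.01 and FOLR1 0.05. In these 9 lists 0 genes passed over all probes by limma, where CCND2, HMOX1 and ACO2 passed adjusted over the list alone, in lists of 2, 3 and 1 measured genes.

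Probes labelled with markers of maternal cells showed no call, which, given the limit of the gene names, cannot show that such cells were absent. Of the endometrial list 5 genes were measured, with ACP5, uteroferrin, at 0.02, LTF at 0.14, FOLR1 at 0.05 and ESR1 at -0.16 (camera adjusted p = 0.851, and 0.884 with an estimated correlation). Of 3 leukocyte genes, CD19 had a change of 0.27, ITGB2 of -0.29 and IL2RG of 0.06. Of 4 genes of uterine stroma, muscle and vessels, PECAM1 had 0.30, DES, above background on 2 control arrays, 0.20, CDH5 0.05 and DCN -0.08. The 12 genes of these 3 lists had adjusted p between 0.172 and 0.959 in limma.

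On average over pairs of arrays, the transcriptomes of experimental and control embryos of the same shape lay farther apart than those within a group. The mean distance, as 1 minus Pearson's r over probes, was 0.0247 between groups and 0.0148 within groups. The difference of 0.00988 was the largest of the 35 splits of the arrays into 4 and 4 (exact permutation test, one-sided, p = 0.0286, the smallest these splits can give). With slide means removed it was 0.0107 (exact p = 0.0286). The correlation was 0.988 to 0.994 among control embryos, 0.969 to 0.991 among experimental embryos and 0.955 to 0.986 between groups. These ranges overlap, and experimental replicate 2 had a mean correlation of 0.9834 to the control group and 0.9826 to its own. Without control replicate 2, 3 or 4 the difference was 0.00849, 0.00638 and 0.00822, with an exact permutation p of 0.0571 each.

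**Figure D3:**
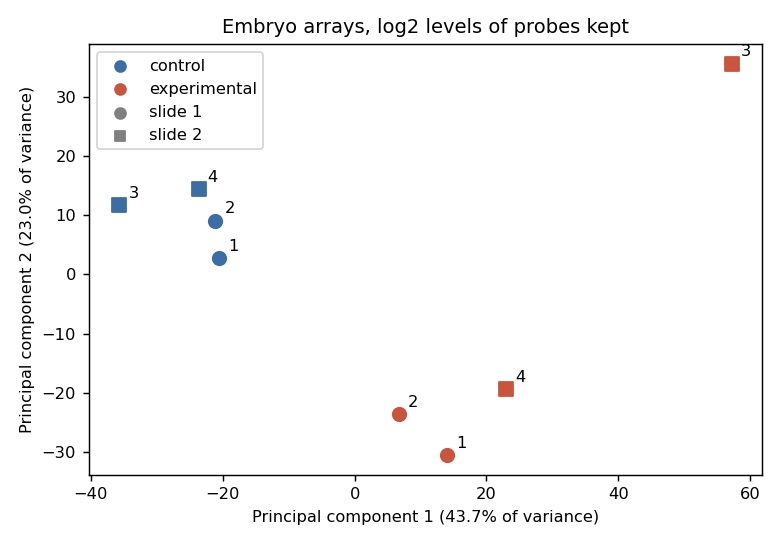
First (horizontal) and second (vertical) principal component of the log2 levels of the probes kept; each point is 1 array with its replicate number, blue control and red experimental, circles slide 1 and squares slide 2. Control arrays lie at the left, between -35.7 and -20.6 on the first component, and experimental replicate 3 lies apart at 57.2.

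Experimental embryos were more spread out than control embryos in these arrays, but the difference did not pass its test. The mean distance within the experimental group was 0.0205, and within the control group 0.00918 (exact permutation test over 70 assignments, two-sided, p = 0.229). The median log2 ratio of the SDs of a probe, experimental over control, was 0.56, and it was -0.06 without experimental replicate 3. Without that array the difference in spread was 0.00247 (exact permutation p = 0.657), against 0.0113 with it.

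The red and green signals of an array measure the same RNA on the same spots, so their ratio shows the technical spread between dyes. Variation that both channels of an array share cancels in the ratio, so it does not measure the technical spread between arrays. The SD over probes of the loess-normalized log2 ratio was 0.117 to 0.124 on control arrays and 0.111 to 0.129 on experimental replicates 1, 2 and 4. It was 0.173 on experimental replicate 3. Tested in the same way as the levels, the dye ratio differed between the groups for 0 probes by limma, with 721 at an unadjusted p under 0.05.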

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

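The tests chosen only after the result was seen were those of spot noise and accessions for the gene labels, of slide and GC content for experimental replicate 3, and of spot noise, slide, overall signal and GC content for the number of changed probes. Of these, both GC tests and that of overall signal replaced a first test whose outcome had been seen, and the first values are given with them. Over 154 sets of 4 arrays, the highest or lowest array stood apart from the rest in 9, where chance gives about 5%, and 6 of the 9 lay in experimental replicate 3.

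Experimental replicate 3 had a mean correlation of 0.9707 to its own group, against 0.982 to 0.9828 for the other 3 arrays. Tables argue against noise of single spots (its deviations had r = 0.8205 between probes that share 30 bases) and against a gain of probes at transcript ends (0.01598 log2). For the slide, its deviations had r = -0.02992 with the slide difference of control arrays. That difference also holds differences between samples, so the value shows no shared slide difference but cannot exclude the slide. The first GC test was undecided (r = 0.281 between the deviations of this array and GC content). In the test that replaced it, removal of GC trends left its gap at 0.8956 of the range, from 0.9389, still beyond the critical value, so GC content is excluded as the whole cause. A sample farther along the difference between the groups stays open, since 3 correlations on arrays not shared were -0.1032, -0.0254 and 0.138. For the other experimental arrays the same correlations ran from -0.239 to 0.232, so these values do not set experimental replicate 3 apart.

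The dye ratio, which the comparison of levels does not use, had an SD of 0.1726 on experimental replicate 3, 0.1288 on experimental replicate 2 and 0.1258 on experimental replicate 4, above the control arrays (0.1173 to 0.1244). In experimental replicate 3 the probe labelled IL1B stood apart at 16.8 (others 17.12 to 17.19), HADHA at 12.81 (13.48 to 13.57), DDX58 at 12.27 (13.06 to 13.13), HSD3B1 at 8.705 (9.149 to 9.22) and MX1 at 9.348 (7.99 to 8.114). CCND2 stood apart at 8.017 in control replicate 2, CDH5 at 7.726 in experimental replicate 2 and ALOX15 at 6.812 in experimental replicate 1.

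For the 999 changed probes and for the 336 changed at least 2-fold, 1 of 35 splits of the arrays gave as many, the real one. The highest other count was 1. This argues against a chance division of these arrays but does not exclude it, since 1 of 35 is the smallest share these splits can give. It also cannot tell the group from a difference in pregnancy, as the labels do not say that the samples came from separate pregnancies. For gene lists chance cannot be excluded, as 18 of 35 splits gave a list p as small as 0.1013 (smallest other 0.005918). Tables argue against noise of single spots (log2 changes had r = 0.9468 between probes that share 30 bases). They also argue against GC content (1075 calls with GC trends removed, after an undecided first test with r = 0.143). The slide as a block left 970 calls. Each slide held equal numbers of arrays of each group, so a shift between slides cancels in the group difference. The 970 calls therefore say nothing more about the slide as a cause. For a gradient along the slide, the step between neighbouring positions had r = -0.04858 between control and experimental arrays, under its bound. These steps also hold differences between samples, so the value cannot decide about a gradient. Overall signal stays open. The first test, the share of increases (47.7%), could not decide, because quantile normalization between arrays constrains that share. In its replacement 91.82% of the probes called higher stayed above 0 with arrays centred on the median of all probes (89.0% to 94.1%, bound 90%). Of the 477 probes called higher, 132 were still called higher there, against 520 of 522 called lower. A step between the slide positions of the groups stays open and cannot be told apart from the group, and so do the age and the population of the embryos, which were not tested separately.

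Probes with the same gene label did not move together. Tables argue against noise of single spots, since the median correlation of 136 pairs that share 30 bases was 0.9136. Accessions that do not mark 1 transcript stay open: of 175 pairs on the array that share 30 bases, 22.29% carry the same accession, which tells of several accessions on 1 sequence and not of several transcripts under 1 accession. Dim probes stay open, since 177 pairs of the same label above the median level had a median correlation of 0.1456 (-0.0429 to 0.293). No biological explanation was tested.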

How the results depend on the processing

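Each slide alone, slide means removed, GC trends removed, centring on the probes kept and the limit to several probes were chosen after seeing the data. The number of changed probes (999) was 2101 with median centring, 1771 centred on the probes kept, 1985 with array weights, 26 with a plain test without variance sharing, 4 and 0 on slides 1 and 2 alone, and 307 to 1332 with 1 array left out. The 2-fold count (336) was 750 from processed signals, 981 with median centring, 12 with the plain test, 4 and 0 on the slides alone, and 158 to 385 with 1 array left out. The next counts are over all measured genes with a symbol, not only those named by the rule. Genes past the test with groups that do not overlap (20) numbered 48 with median centring (13 of the 20 still had an adjusted p under 0.05), 37 centred on the probes kept, 35 with array weights, 1 with the plain test, 0 on each slide alone, 7 with at least 2 kept probes in 1 direction, and 7 to 33 with 1 array left out. Single slides and left-out arrays have fewer samples; for the other settings the cause was not tested.

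The list count (0) was 1 with fry. Without the filter, uterine stroma reached 5 genes (adjusted p = 0.656 by camera in limma). The difference between and within groups (0.00988) kept its direction in 23 alternatives and was 0.00638 to 0.0134 with 1 array left out, with p = 0.0571 (exact) without control replicate 2, 3 or 4. The dye ratio SD (0.122) was 0.227 from processed signals and 0.149 with offset 16. Of 1928 values of named genes under alternatives, 183 lost the call and 23 gained it. Sign changes occurred in 61 of them and 18 list values, each called under neither setting and counted here as keeping its side. The scan block equals the slide block, since each slide was scanned once.

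The labels do not state that the replicate numbers pair the samples, and the correlations cannot decide it. Deviations of same-numbered samples had r = 0.142, 0.0124, -0.149 and 0.047, and not every sample correlated best with its own number. With the replicate block 148 probes, 103 at 2-fold and 3 named genes were called, and no list call changed. The series table was not run as an alternative, because it holds ratios of 1 sample. Signal over background limited the tests to 19696 of 39513 probes.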

Other observations

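The test of probes with repeated words was chosen after the result was seen, in place of a first test. Among the 999 probes called, 21 were not well above background on any control array and 23 on any experimental array. Probes with a gene name made up 697 of the probes kept, and 20 of their 327 genes were called.

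Probes on opposite strands of the same sequence were also compared. For 210 pairs of kept probes that share 20 bases on opposite strands, the median correlation over arrays was 0.46 and 75.2% changed in the same direction. For 1006 pairs on the same strand these values were 0.871 and 78.8%, and for random pairs 0.003 and 49.6%. The probes of an opposite-strand pair cannot both be sense to the same transcript over the shared bases. How far antisense probes reach beyond such pairs is a question that the data leave open. Of 3493 probes with a forward polyadenylation signal 62.0% were kept, and of 1546 with its reverse complement 52.9%, while 48.5% of probes with neither were kept. The difference of 9.164 percentage points lies between the bounds set at 5 and 10.

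Of 653 kept probes that hold a 16-base word found in at least 10 probes, 4 (0.613%) were called, against 5.23% of the others. This difference was the first test of a shift of these probes between the groups and met its prediction (Fisher's exact test, two-sided, p = 1.45e-10). It was replaced after its outcome was seen, because the prediction named no direction and the share called was lower, not higher. In its replacement the median log2 change of these probes exceeded that of the others by 0.13 (0.1302), and 18 of 35 splits gave a difference as large, so a shift together was not borne out.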
